A study of Mus musculus with 3 samples.

How the data were processed

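Whole-transcriptome RNA sequencing reads from mouse primordial germ cells (PGCs), the embryonic precursors of sperm and eggs, were analysed in 3 libraries of male E11.5 embryos. Per the labels, 2 libraries lacked Ring1 and kept Rnf2 (Rnf2 intact, replicates 1 and 2) and 1 library lacked both genes (Rnf2 deleted, replicate 1). The title of the Rnf2-deleted library gives replicate 1 while the name in its file header ends in 2, and the title was followed. Ring1 and Rnf2 encode the E3 ubiquitin ligases of Polycomb repressive complex 1. Per the labels' protocols, PGCs carrying an Oct4-GFP transgene were sorted by flow cytometry, RNA from small numbers of cells per embryo was amplified to cDNA with the NuGEN Ovation kit, and libraries were made with a TruSeq DNA kit, which keeps no strand. The labels say nothing more on the independence of the samples, so p-values measure only the spread between these samples, which may be technical.

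The authors deposited aligned reads as intervals, and the count in each deposited line, from the values, was the number of copies of that read sequence in the library. Each line was 1 read at 1 place, and a read with several places was listed at each. The genome build mm9, CASAVA 1.8.0 and Bowtie are named per the submitters' processing notes, with no role or order, and the Bowtie version, alignment limits and filters are not given in the sources used here. Interval ends passed the mm10 chromosome length on 9 of 22 chromosomes and the mm9 length on 0, so the coordinates were treated as mm9 (chromosome lengths from GenomeInfoDb 1.38.1).

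The gene annotation at hand belonged to a later mouse build, and coordinates were not converted. Reads were therefore counted by their start in fixed 10 kb windows of mm9, the choice made for this case before the data were examined. The mitochondrial chromosome has a length of 16299 bases in both builds, although the sequences were not compared, so its genes were counted with the annotation, for reads lying within exactly 1 gene. Of the 21 gene lists fixed before the data were examined, only the mitochondrially encoded genes were tested. Ring1, Rnf2 and the other lists were not analysed here, so the genotypes in the labels were not checked against the reads.

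Windows were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr with a minimum count of 10, the quasi-likelihood test and Benjamini-Hochberg adjustment with a threshold of 0.05. The design left 1 residual degree of freedom, and the single Rnf2-deleted library was assumed to vary like the Rnf2-intact pair. The standard error of a fitted log2 fold change was taken as its size divided by the square root of the F statistic. TMM moved the Rnf2-deleted library by 0.11 on the log2 scale against library size alone. A rule of size without a test counted windows with a mean of at least 5 CPM (alignments scaled to the library total) and at least a 2-fold difference in the same direction from each of the other libraries, on log2(CPM + 1). The same rule was applied with each Rnf2-intact library in the place of the Rnf2-deleted one, as a comparison, although the pair it was then set against held both genotypes, so those counts mix differences of genotype and of replicate. The mitochondrial list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and its median was ranked among 10000 random lists matched on mean expression in 20 bins. Since other genes were not counted, camera and the random lists set these genes against 10 kb windows, not against other genes. The highest expression bin also held windows under 50 CPM, so the most read mitochondrial genes were matched only loosely.

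Named windows were the 12 highest and the 12 lowest by the smaller of the log2 ratios to the Rnf2-intact libraries, with a mean of at least 5 CPM and the same direction against both. Windows that did not pass the test were given as values. Bins of 1 kb with at least 1 CPM, or 5 CPM, in 1 library and at most 0.1 CPM in both others were counted from reads at 1 place. A fold against a library with 0 reads was computed against a floor of 3 reads in that library. Exact (Clopper-Pearson) 95% intervals were used for shares, and intervals and floors cover counting error only, since amplified reads are not independent molecules. Alternatives were DESeq2 size factors, library size alone, other filters, pseudocounts of 0.1 and 5 CPM, each position counted once, reads at 1 place only, no mitochondrial reads, 50 kb windows, DESeq2 1.42.0, limma voom and the omission of each Rnf2-intact replicate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for counting, rules of size and plots.

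The method was tested on simulated data drawn from the means, library sizes and fitted dispersions of the 85198 tested windows. Changes were placed in the single library, only in windows with a mean of at least 5 CPM. Each window took the dispersion of the fitted trend at its mean, so windows of like mean did not differ in spread. The method may thus recover other shares in the real libraries than in this simulation. It recovered 5.97% of 67 windows changed 4-fold, 43.3% of 67 changed 16-fold and 62.1% of 66 changed 64-fold, with 12 calls among unchanged windows. With a dispersion of 0.01 it recovered 100% at each size.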

Results

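Transcripts were measured in Ring1-null male PGCs at E11.5, in 2 libraries with intact Rnf2 and 1 library with Rnf2 deleted. The comparison addressed which transcripts differ when the second Polycomb repressive complex 1 ligase is lost from cells that already lack the first. The deposited alignments numbered 36676991 and 38309983 in Rnf2-intact replicates 1 and 2 and 37545608 in the Rnf2-deleted library. They came from 34258991, 35433127 and 34834171 reads, of which 4.50%, 5.08% and 4.86% aligned at several places. Distinct positions made up 67.9%, 65.4% and 67.5% of alignments.

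The mitochondrial chromosome held 7.68% of alignments in Rnf2-intact replicate 1 (95% exact interval 7.67% to 7.69%), 8.29% in replicate 2 (8.29% to 8.30%) and 7.62% in the Rnf2-deleted library (7.61% to 7.63%). Chromosome X held 2.42%, 2.43% and 2.54% of alignments in the same order, and chromosome Y held 0.0368%, 0.0486% and 0.0397%. After the mitochondrial chromosome, the window with the most reads was chromosome 17, 39980001 to 39990000 (mm9), with 992330, 1147041 and 794130 reads. Its fitted log2 fold change, Rnf2 deleted over intact, was -0.54 (SE 0.09), with an adjusted p of 0.868 by edgeR. The 12 windows with the most reads held 13.2%, 14.3% and 12.3% of alignments.

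The Rnf2-deleted library did not stand apart from the Rnf2-intact pair in correlations across windows of at least 5 or 20 CPM. Across the 37108 windows with a mean of at least 5 CPM, Pearson's r of log2(CPM + 1) was 0.613 for the Rnf2-intact pair, 0.555 for the Rnf2-deleted library with replicate 1 and 0.611 with replicate 2. Spearman's rho was 0.602, 0.545 and 0.597, and the SD of the log2 ratio was 1.157, 1.203 and 1.144. At a mean of at least 20 CPM, r was 0.624, 0.584 and 0.676 and rho 0.488, 0.436 and 0.551 in the same order, so the Rnf2-deleted library was closest to replicate 2. Windows are not independent replicates. Across all 154142 windows with reads, r was 0.880, 0.857 and 0.867 and rho 0.717, 0.697 and 0.704. The SD of the log2 ratio was 0.854, 0.930 and 0.894 there, so without a minimum the Rnf2-intact pair was closest. The chi-square of the counts was 107.9 per degree of freedom for the Rnf2-intact pair and 114 and 103.9 for the Rnf2-deleted library with replicates 1 and 2. The pair was thus not 1 library deposited as 2, and whether its RNA samples were independent was not tested.

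No single 10 kb window passed the test for a change with Rnf2 deletion, although individual windows showed large differences in reads. On chromosome 7, 54090001 to 54100000 held 3953 reads in the Rnf2-deleted library against 0 and 4 in the Rnf2-intact libraries, or 105.3 CPM against 0.0522 ± 0.0738 CPM (SD, n = 2). On chromosome 1, 138600001 to 138610000 held 28 reads against 1282 and 1439, or 0.746 CPM against 36.3 ± 1.84 CPM (SD, n = 2). The edgeR and limma voom fits used the 85198 windows that passed the count filter, and DESeq2 used all 154142 windows with reads. Of 85198 windows tested by edgeR, 0 were past the threshold and 4069 had an unadjusted p under 0.05, where 4260 would be reached by chance. The smallest adjusted p was 0.804. limma voom called 0 windows, with 7307 at an unadjusted p under 0.05 against the same 4260 by chance, and DESeq2 called 2300, of which 1229 were higher and 1071 lower. With Rnf2-intact replicate 1 or 2 in the place of the Rnf2-deleted library, DESeq2 called 2089 and 1868 windows, and voom gave 2188 and 1110 at an unadjusted p under 0.05, in fits whose remaining pair held both genotypes. In 50 kb windows edgeR called 0, with 1903 at an unadjusted p under 0.05 against 1411 by chance, and with 1231 and 901 when replicate 1 or 2 was set apart.

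The 12 named windows with higher values lay on 8 chromosomes, and their smaller log2 ratios ran from 4.58 to 6.59. The window at chromosome 10, 119860001 to 119870000, held 1846 reads against 3 in each Rnf2-intact library, a ratio of 601 to replicate 1 (95% exact interval 205 to 2917). At chromosome 10, 82600001 to 82610000, 1634 reads stood against 2 and 0. At chromosome 11, 5880001 to 5890000, 1002 reads stood against 0 and 0, at least 326-fold higher than replicate 1 and 341-fold higher than replicate 2, each at its floor. Chromosome 5, 124950001 to 124960000, held 1119 reads against 4 and 3, and chromosome 2, 27210001 to 27220000, held 1669 against 0 and 34. The fitted log2 fold change of the chromosome 7 window was 10.76 (SE 1.06), with an adjusted p of 0.804 by edgeR. That window passed with a mean of at least 10 CPM (adjusted p = 0.0350 by edgeR), and it passed with both chromosome 10 windows with reads at 1 place only (adjusted p = 0.000418, 0.0177 and 0.00771). Under those settings edgeR called 1 and 3 windows with the Rnf2-deleted library set apart, against 4 and 33 with Rnf2-intact replicate 1 in its place and 2 and 9 with replicate 2.

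The 12 named windows with lower values also lay on 8 chromosomes, and their smaller log2 ratios ran from -4.36 to -3.55. Chromosome 18, 43030001 to 43040000, held 1 read in the Rnf2-deleted library against 632 and 595. Chromosome 9 had a pair of them, 68550001 to 68560000 with 30 reads against 1035 and 796, and 68700001 to 68710000 with 13 against 814 and 740. Between them lay a run of 5 neighbouring windows, 68590001 to 68640000, each at least 2-fold lower, with 435 reads against 3005 and 3463. Chromosome 1 also had a pair, the window at 138600001 and 138510001 to 138520000, which held 3 reads against 485 and 450. Chromosome 5, 115130001 to 115140000, differed within the Rnf2-intact pair, with 498 and 1586 reads against 1. The adjusted p of all 12 was 0.868 by edgeR.

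**Figure D1:**
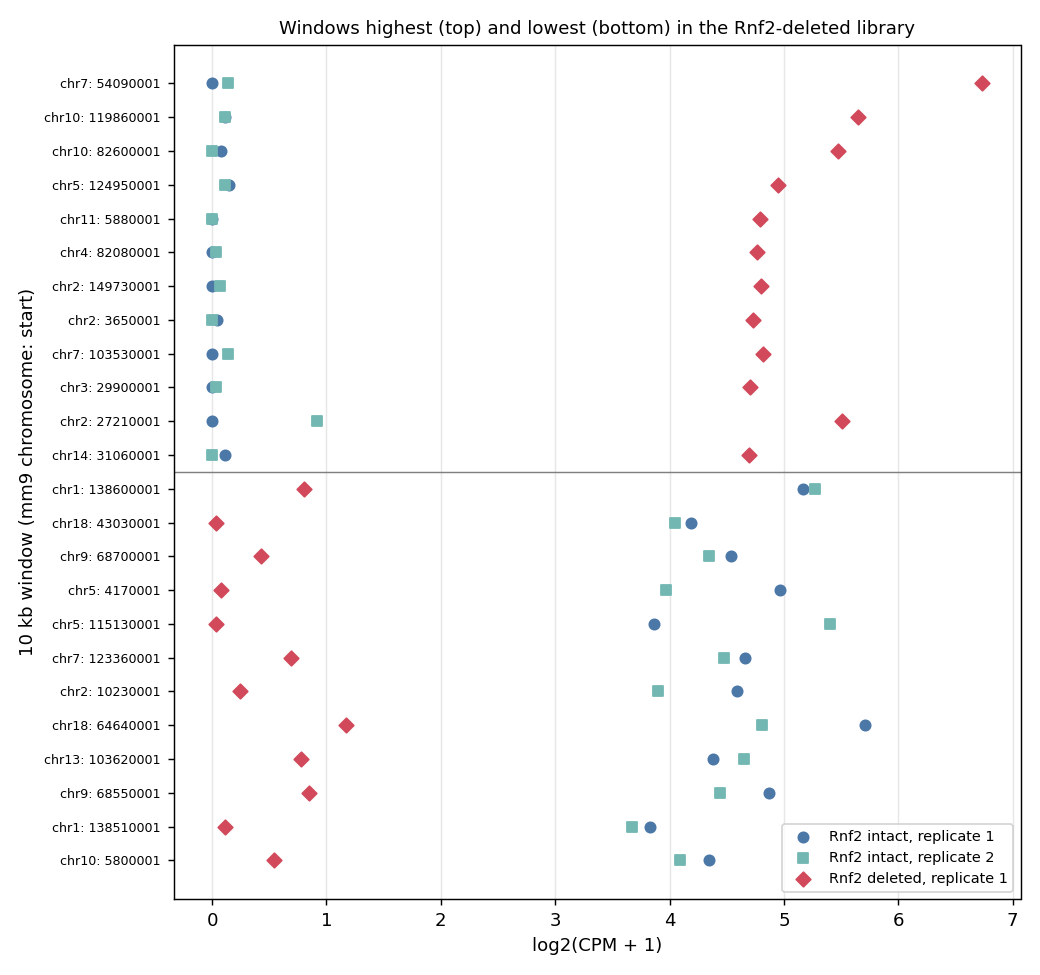
Points show log2(CPM + 1) on the horizontal axis for each library in the 24 named 10 kb windows, listed by mm9 chromosome and start on the vertical axis. The Rnf2-deleted library lies to the right of both Rnf2-intact libraries in the upper 12 windows and to the left in the lower 12, and none passed the edgeR test.

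By the rule of size, 2518 windows were at least 2-fold higher and 2727 at least 2-fold lower in the Rnf2-deleted library than in both Rnf2-intact libraries. These were 14.1% of the 37108 windows. The same rule gave 2973 higher and 2633 lower for Rnf2-intact replicate 1, or 15.1%, and 1881 higher and 2889 lower for replicate 2, or 12.9%. The split depended on scaling. After TMM scaling the Rnf2-deleted library had 2087 higher and 3245 lower, replicate 1 had 3242 and 2439, and replicate 2 had 2159 and 2633. At this minimum the total for the Rnf2-deleted library lay between those of the Rnf2-intact replicates, but at a mean of at least 50 CPM it was the highest, with 54 windows against 48 and 33 (69 against 57 and 32 after TMM scaling). The split turned to more higher than lower windows without a filter (11674 and 4367), with a pseudocount of 5 CPM (1540 and 1123) and without Rnf2-intact replicate 1 (5974 and 5432), and was 5879 and 6636 without replicate 2. Counts with a Rnf2-intact replicate set apart are not given for these settings, so the turn cannot be called particular to the Rnf2-deleted library. Among the 11830 windows with a mean of at least 20 CPM, the Rnf2-deleted library had 232 higher and 539 lower, replicate 1 had 527 and 360, and replicate 2 had 245 and 343. After TMM scaling these were 162 and 717, 600 and 304, and 305 and 291, which turned the direction of the split in replicate 2. In 50 kb windows, chosen after seeing the data, the Rnf2-deleted library had 1309 higher and 642 lower, replicate 1 had 744 and 992, and replicate 2 had 398 and 1100, or totals of 1951, 1736 and 1498.

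**Figure D2:**
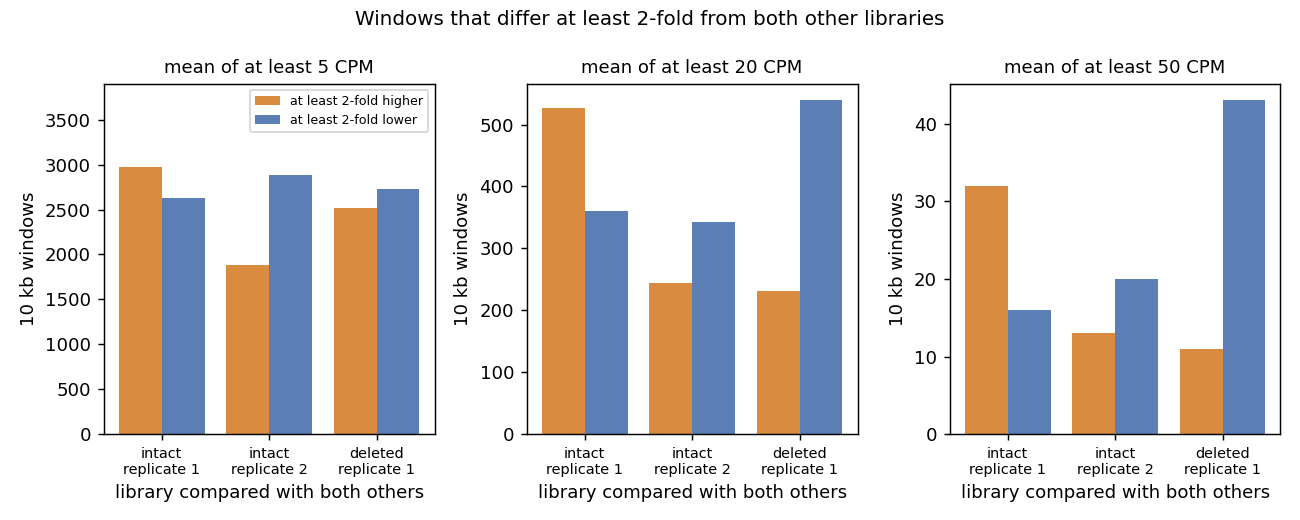
Bars show the number of 10 kb windows at least 2-fold higher or lower in each library than in both others, in 3 panels by mean CPM, with axes that start at 0. At a mean of at least 5 CPM the 5245 windows of the Rnf2-deleted library lie between the 5606 and 4770 of the Rnf2-intact replicates.

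Mitochondrially encoded genes, which specify respiratory chain subunits and mitochondrial ribosomal RNAs, showed no change with Rnf2 deletion that passed the test. Of the 15 genes in the list, 15 were measured, 0 passed the threshold over all features, 0 passed when adjusted over the list alone, and 2 had an unadjusted p under 0.05 by edgeR. Those were the ribosomal RNA genes. With reads at 1 place only, 9 of the 15 genes passed the count filter, so nearly all reads of the others aligned at several places. The values of those others may hold reads from outside the mitochondrial chromosome, which was not tested. mt-Rnr1 (mitochondrial chromosome, 70 to 1024) was at 7049 CPM against 8497 ± 289 CPM (SD, n = 2), with a log2 fold change of -0.38 (SE 0.10) and, by edgeR, an adjusted p of 0.868 over all features and 0.108 over the list alone (0.0427 over the list alone with DESeq2 size factors). mt-Rnr2 (1094 to 2675) had a log2 fold change of -0.17 (SE 0.07) and an adjusted p of 0.247 over the list alone by edgeR. Among the protein-coding genes, mt-Co1, a cytochrome c oxidase subunit, had a log2 fold change of -0.18 (SE 0.14), mt-Nd4, a complex I subunit, 0.18 (SE 0.20), and mt-Nd6, another, 0.49 (SE 0.62). The list median was 0.02, with 8 genes above 0 and 7 below (10 and 5 with library size alone, 2 and 13 with each position counted once), at percentile 83.4 of random lists of 10 kb windows. The camera p was 0.656 (0.894 with an estimated correlation) and the fry p was 0.989, both with a downward direction against the positive median.

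**Figure D3:**
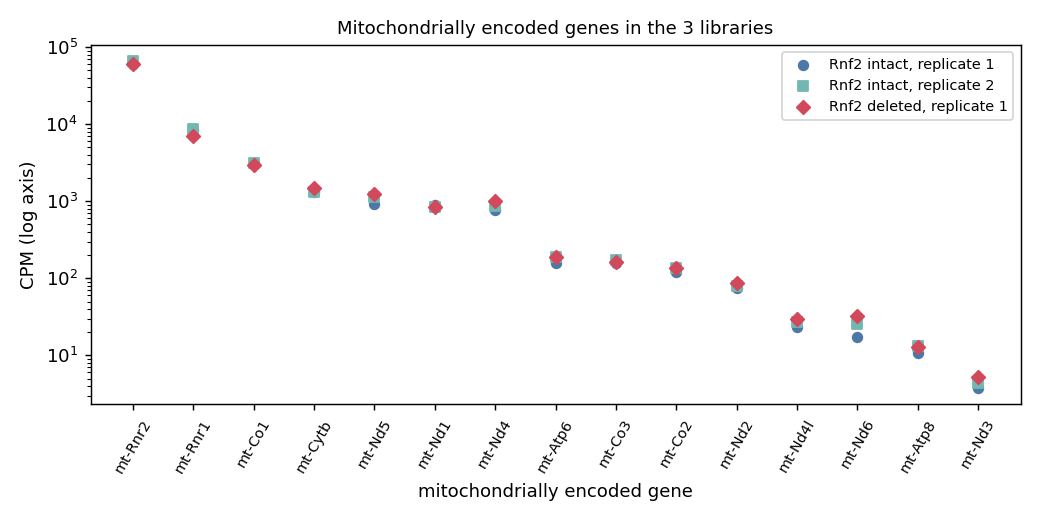
Points show CPM on a log axis for the 15 mitochondrially encoded genes in the 3 libraries, with reads at several places included. mt-Rnr2 lies highest, at 60636, 66109 and 60740 CPM, and no gene passed the edgeR test.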

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

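The settings with TMM-scaled CPM, 50 kb windows and reads at 1 place in the rule of size were chosen after seeing the data, as was the 50 kb fit with a mean of at least 10 CPM. With that filter on 50 kb windows, fewer had an unadjusted p under 0.05 by edgeR with the Rnf2-deleted library set apart than with Rnf2-intact replicate 1. More did than with replicate 2. Windows past the threshold numbered 0 with DESeq2 size factors, library size alone, no filter, positions counted once, no mitochondrial reads, 50 kb windows with or without that filter and limma voom (edgeR gave 4069 at an unadjusted p under 0.05 and DESeq2 2300 calls), 1 with a mean of at least 10 CPM and 3 with reads at 1 place only, and the cause was not tested. Of 207 alternative tests of the 24 named windows, 28 put a window past the threshold, 24 of them by DESeq2, and their direction was set by how they were chosen. By the rule of size, windows higher and lower were 1540 and 1123 with a pseudocount of 5 CPM, 11674 and 4367 without a filter, 232 and 539 at a mean of at least 20 CPM, and 1309 and 642 in 50 kb windows, where filters and window size changed the number of windows compared. With TMM-scaled CPM windows higher and lower were 2087 and 3245, against 2518 and 2727 in the main setting. Without 1 Rnf2-intact replicate they ran from 5879 to 5974 and from 5432 to 6636, since only 1 library was left to differ from. The mitochondrial median was -0.0815 with positions counted once, a count that saturates on a chromosome this short, and ran from -0.10 to 0.12 without 1 Rnf2-intact replicate. Pearson's r of the Rnf2-intact pair was 0.613 and 0.624 at a mean of at least 5 and 20 CPM, where low windows no longer entered. No paired analysis was possible because the labels give no link between samples of the groups, and a shared replicate number is not a pairing. Whole gene bodies and the omission of ribosomal RNA genes were not run. Depth limited windows with few reads, and 1 Rnf2-deleted library limited every comparison.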

Other observations

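The tests on genomic DNA, on thinned libraries, on distinct positions, on copies of library fragments and on TMM scaling, and the counts of neighbouring windows, were chosen after the patterns they bear on had been seen. Windows lower in the Rnf2-deleted library lay beside each other in 334 pairs, against a mean of 136 when windows of like expression were shuffled 1000 times. The same count was 206 against 126 for Rnf2-intact replicate 1 and 306 against 153 for replicate 2. For higher windows it was 209 against 116 in the Rnf2-deleted library, 295 against 162 in replicate 1 and 104 against 64.2 in replicate 2. Runs of at least 3 lower windows numbered 53 in the Rnf2-deleted library, 19 in replicate 1 and 33 in replicate 2, and runs of higher windows 27, 39 and 10. Runs in the Rnf2-deleted library included chromosome 15, 34820001 to 34870000, with 454 reads against 3064 and 2697, and chromosome 11, 54430001 to 54480000, with 1199 against 3382 and 4109. Runs with higher values included chromosome 4, 82100001 to 82150000, with 4168 reads against 430 and 198, and chromosome 15, 27900001 to 27940000, with 3665 against 346 and 116.

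More of the genome had reads in the Rnf2-deleted library alone: 21391 bins of 1 kb held at least 1 CPM there and at most 0.1 CPM in both other libraries, against 15693 and 13870 for Rnf2-intact replicates 1 and 2, and at least 5 CPM left 2236 against 1952 and 1366. Thinning to equal reads left a ratio of 1.38 to the higher Rnf2-intact library. The libraries differed so little in reads that thinning could hardly have changed it. Rnf2-intact replicate 2 had the most alignments, 38309983, and the fewest such bins, which argues against depth. Evenly sampled genomic DNA as the whole source is argued against by Pearson's r of 0.880 over 19 autosomes between the density of these bins and that of bins read in all 3 libraries (permutation p = 1e-05, the smallest they can give, adjusted 2e-05, Spearman's rho 0.814 with permutation p = 3e-05, adjusted 3e-05, r = 0.806 without chromosomes 11 and 19), but a part from genomic DNA stays open, since uneven sampling was not tested and the density on chromosome X relative to autosomes was 0.509, close to the 0.5 of male DNA, against 0.372 for bins read in all libraries and 0.593 and 0.617 for bins read in Rnf2-intact replicate 1 or 2 alone. The correlation covered all 21391 bins, so it did not test the excess over the Rnf2-intact libraries by itself. Evenly sampled DNA would give like values across the genome. In the Rnf2-deleted library 60645 windows of 10 kb reached 1 CPM, of 154142 with reads in any library. Each of the 21391 bins held that much in 1 kb. This argues against evenly sampled genomic DNA as the source of these bins or of their excess. Copies of single library fragments are argued against by the reads of these bins, a median of 63 per bin at a median of 60 distinct positions, while copies of single cDNA molecules sheared after amplification were not tested. Chance sampling of rare molecules before amplification and Rnf2 deletion itself also stay open as untested explanations, with 1 library in the group.

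Among windows with a mean of at least 20 CPM, the count of lower windows in the Rnf2-deleted library was 1.497 times that of the higher Rnf2-intact replicate. At a mean of at least 50 CPM the count was 43 against 16 and 20 for replicates 1 and 2. Without TMM scaling this excess was absent at a mean of at least 5 CPM, in 10 kb windows (2727 against 2889) and 50 kb windows (642 against 1100). After TMM scaling it was present in 10 kb windows at that minimum, with 3245 lower windows against 2439 and 2633. At a mean of at least 20 CPM the ratio was 2.36 after TMM scaling, with 162 higher and 717 lower windows. This does not decide whether scaling was the cause. The TMM factor was 1.054 for the Rnf2-deleted library and 0.977 and 0.972 for Rnf2-intact replicates 1 and 2. TMM thus lowered the Rnf2-deleted library against both others, which by itself adds lower windows, and no scaling in the other direction was tried. Copies of library fragments are argued against as the whole cause by a ratio of 1.46 with each position counted once, but copies made in amplification cannot be told apart, because cDNA was amplified before shearing and its copies lie at different positions, which the bound set for that test had overlooked. The test and its bound had been set for copies made in amplification, and their use for library fragments was written afterwards. A smaller imbalance in the other direction occurred for Rnf2-intact replicate 1, with 527 higher and 360 lower windows (600 and 304 after TMM scaling). Differences between single samples and Rnf2 deletion both stay open, since 1 Rnf2-deleted library was analysed here.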
